A study of Mus musculus with 20 samples.

How the data were processed

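Total RNA from the livers of 20 mice was hybridised to Affymetrix mouse arrays, 1 array per animal, with 5 animals in each of 4 groups. The groups combine genotype (progeroid Ercc1Δ/- or wild type) with diet (control or restricted), and each group was taken from the source name of the sample. The sample labels also carry the number of the animal. The 4 groups share no animal numbers, so no animal was paired with another. The labels name separate animals, so the spread between arrays of a group includes the spread between mice.

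The deposited values are on the log2 scale and were made with RMA, per the submitters' processing notes; its version and the array definition are not given in the sources used here. RMA corrects background, sets all arrays to the same distribution and summarises the probes of a probe set, so an overall shift of expression between groups would be removed. The deposited table holds 45141 probe sets per array with values from 2.19 to 14.51, and array medians lay between 4.17 and 4.21. The number of arrays limits the precision. RMA values have no zero point, and near the lower end of the scale they understate folds.

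Probe sets were named from the platform annotation supplied with the values, with symbols checked by Entrez ID against a table of RefSeq genes of assembly GRCm38.p6; 28689 of 28898 probe sets with 1 symbol were found there and 0 symbols changed. A further 551 probe sets carried several symbols and 15588 had no symbol here, and none of these was used for a gene. The 104 control probe sets were left out. Each of 17097 genes was represented by the probe set with the highest mean over the 20 arrays; 7180 genes had more than 1 probe set. No filter on dim probe sets was applied. In the wild type control group 8276 genes had a mean under 5 on the log2 scale.

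A model with 1 mean per group was fitted to all 20 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 16 residual degrees of freedom before moderation), and 5 contrasts were taken from it: the genotype effect on each diet, the diet effect in each genotype, and the difference of the diet effects (progeroid minus wild type). P-values were adjusted by Benjamini-Hochberg within each contrast, and a gene was said to rise or fall at an adjusted p under 0.05. All tests are two-sided. Errors of log2 fold changes are moderated standard errors (SE) and those of group levels are standard deviations (SD), with n = 5 per group throughout.

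Membership of 37 gene lists, covering pathways and markers of cell types, was fixed before the data were examined, as were the tests of the comparisons, the contrasts and the alternatives. Some tests of explanations were chosen later. Each list was tested in each contrast with camera at a preset correlation of 0.01, adjusted over all 185 tests. Of these, 67 passed. With a correlation estimated from the data 0 passed after adjustment and 24 had an unadjusted p under 0.05, and the lowest adjusted p was 0.106. With fry, which asks whether a list moves one way and does not compare it with other genes, 57 passed, among them 46 of the 67. Some lists share members. Genes named in the text follow a rule fixed in advance: in each contrast the 4 largest rises and 4 largest falls among genes past the threshold, with no overlap between the groups in pairwise contrasts and without provisional symbols; from each list the 2 members with the smallest adjusted p in the first 3 contrasts; Ercc1; and sex-linked genes. The rule gave 200 results, each a gene in a contrast. Which of them the text prints was chosen after their values were seen, so the counts of results that kept their call under the alternatives cover all 200. Values of a named gene are also given for other contrasts. Chance gives no overlap between groups of 5 for 0.794% of genes.

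The similarity of effects was measured by Pearson's correlation across genes, which are not independent replicates, with a jackknife over animals for its error. For contrasts that share the wild type control arrays, unchanged groups were simulated from the residuals 100 times, and the controls were also split into 2 and 3 arrays in all 20 ways. Single values per animal were compared by exact permutation tests over 252 assignments, which cannot give a p below 0.00794.

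The fit was tested on simulated data for 17097 genes with the spread of the real ones and 50 changed genes at each of 4 fold sizes per comparison. For the genotype effect on control diet it recovered 42% of 1.25-fold changes, 76% of 1.5-fold changes and 100% of 2-fold changes, with 8 false calls. For the difference of diet effects it recovered 14% of 1.25-fold changes, 62% of 1.5-fold changes and 90% of 2-fold changes, with 7 false calls. The simulated genes varied independently, and fewer of them changed than were called in the real pairwise comparisons. The adjusted threshold depends on how many genes change, so these rates need not carry over to the real data.

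Alternatives were per-array median centring, removal of the lowest tertile of genes by mean, a test of all probe sets, removal of probe sets ending in _x_at, _s_at or _a_at, the mean of all probe sets of a gene, fits of only the groups compared, a trended robust prior, array weights, a covariate made of the mean of Y-linked genes minus Xist, a fold minimum of 1.5, and leaving out each animal in turn. A planned comparison of long with short genes was not run, and the table of RefSeq genes was used only to check symbols.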

Results

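Gene expression was measured in the livers of 20 mice aged 11 weeks. Ercc1 encodes a subunit of a structure-specific endonuclease that works in nucleotide excision repair and in the repair of interstrand crosslinks. Ercc1Δ/- mice, called progeroid here because they age early, were compared with wild type littermates from the same cross of C57BL6J and FVB parents. In each genotype 5 mice had the control diet and 5 had restricted food. Restriction began at 7 weeks with a reduction of 10% and reached 30% at 9 weeks. Restricted wild type mice then received 2.1 g of food per day, while freely fed wild type mice ate 3.0 g. The protocol also gives 1.6 g per day for 30% restriction without naming a genotype, which is read here as the amount for progeroid mice. The comparisons ask what the repair defect changes in the liver, what restriction changes in each genotype, and where the response to restriction differs between them.

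The arrays correlated with each other between 0.979 and 0.997 across genes, and 0 pairs held identical values. The first principal component carried 35.6% of the variance and the second 22.2%. On the second, every progeroid array lay above every wild type array. Within each genotype, restricted animals lay above controls on the first. The labels give no sex; Eif2s3y, a Y-linked gene, lay between 9.58 and 10.19 in all 20 arrays, and the Xist probe set with the highest signal did not exceed 4.50.

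**Figure D1:**
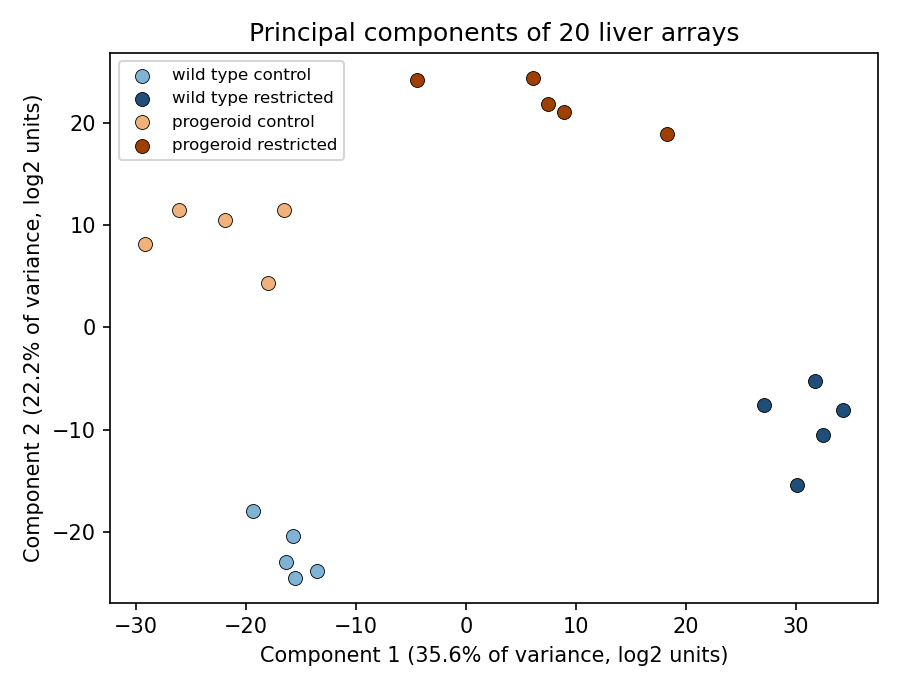
Scores of the 20 liver arrays on the first 2 principal components of all 17097 genes (35.6% and 22.2% of the variance; log2 units), 1 point per animal, coloured by group. The 4 groups form separate clusters, with the restricted wild type animals between 27.07 and 34.26 on the first component.

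Ercc1 was lower in the progeroid livers on both diets. Its level was 6.54 ± 0.07 (SD, n = 5) in wild type control mice and 5.30 ± 0.15 in progeroid control mice, a 2.35-fold fall (log2 fold change -1.24 ± 0.098 SE; limma adjusted p = 8.73e-08). On the restricted diet it was 6.15 ± 0.12 in wild type and 4.80 ± 0.24 in progeroid mice, a 2.56-fold fall. A second probe set of the gene fell by 1.60 between the control groups on the log2 scale, whereas the other 2 probe sets, near 4.83 and 4.59 in wild type control mice, differed by 0.020 and -0.034. Which of the probe sets lie in the altered part of the gene was not determined here. Without probe sets ending in _x_at, _s_at or _a_at, 1 of these flat probe sets stands for Ercc1 and the difference is 0.020.

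On the control diet, progeroid livers differed from wild type livers most in Afp, which encodes alpha-fetoprotein of fetal liver. It rose 18.8-fold (log2 fold change 4.23 ± 0.17 SE, n = 5 per group), from 4.12 ± 0.12 to 8.35 ± 0.14. Pls1, which encodes the actin-bundling protein plastin 1, rose 10.7-fold (3.42 ± 0.22), Sult1e1, an estrogen sulfotransferase, 9.51-fold (3.25 ± 0.51), and Lcn2, the iron-carrier-binding lipocalin 2, 7.54-fold (2.92 ± 0.25). The largest falls were those of Mfsd2a, a lysophospholipid transporter (8.71-fold; -3.12 ± 0.41), Sult5a1 (5.22-fold; -2.38 ± 0.24), Serpina12 (4.93-fold; -2.30 ± 0.28) and Serpina4-ps1 (4.80-fold; -2.26 ± 0.49). In all, 1145 genes rose and 738 fell of the 17097 tested.

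Of 24 measured targets of p53, 12 rose in the progeroid livers and 12 did not pass the test, with 13 higher when adjusted over the list alone. Cdkn1a, which encodes the cell cycle inhibitor p21, rose 4.04-fold (log2 fold change 2.02 ± 0.27 SE) and Phlda3, an inhibitor of AKT, 3.96-fold (1.99 ± 0.29). The camera adjusted p of the list was 2.58e-06, and its adjusted p = 0.195 with an estimated correlation. Of the senescence and secreted factors, 4 of 12 rose (also 4 adjusted over the list alone), among them Cdkn1a and Mmp12, a macrophage elastase, which rose 3.15-fold (1.65 ± 0.22). That list passed camera at 0.00481, with adjusted p = 0.195 with an estimated correlation. Of the cell cycle genes 4 of 30 rose, and 4 adjusted over the list alone. Mcm6 rose 2.40-fold (1.26 ± 0.17) and Mcm4 1.68-fold (0.75 ± 0.14); both belong to the replicative helicase. Camera gave 0.00123 for this list, and adjusted p = 0.54 with an estimated correlation. Among genes of nucleotide excision and crosslink repair 3 of 24 rose and 2 fell, 1 of which is Ercc1 itself (5 and 3 adjusted over the list alone). Rpa1, a single-strand DNA binding protein, rose 1.45-fold (0.54 ± 0.08), and camera gave 0.62 for the list.

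Interferon response genes rose more widely than any other list on the control diet: 17 of 24 rose, 7 did not pass, and 19 rose when adjusted over the list alone. Usp18, a protease that removes ISG15, rose 4.48-fold (log2 fold change 2.16 ± 0.28 SE) and Xaf1 2.44-fold (1.29 ± 0.16). The camera adjusted p was 1.32e-13, with adjusted p = 0.238 with an estimated correlation. Some markers of other cells rose in the same livers. Of the Kupffer cell and macrophage markers 2 of 12 rose (6 adjusted over the list alone), including Vsig4 at 1.51-fold (0.59 ± 0.13); camera gave 0.00168, and adjusted p = 0.598 with an estimated correlation. Of the neutrophil and monocyte markers 4 of 11 rose (4 adjusted over the list alone), with S100a8 at 2.77-fold (1.47 ± 0.19) and S100a9 at 2.76-fold (1.47 ± 0.18). Camera gave 0.00707 for that list, and adjusted p = 0.195 with an estimated correlation. Stellate cell and fibrosis markers rose in 5 of 14 cases (6 adjusted over the list alone), among them the matrix proteoglycans Lum at 1.93-fold (0.95 ± 0.13) and Dcn at 1.40-fold (0.48 ± 0.08). Their camera adjusted p was 0.00154, with adjusted p = 0.36 with an estimated correlation. Acute phase genes rose in 6 of 22 cases (10 adjusted over the list alone), including Lcn2 and the haemoglobin scavenger Hp at 1.21-fold (0.28 ± 0.06); camera gave 0.000941, and adjusted p = 0.444 with an estimated correlation. The difference between 3' and 5' probe sets of Gapdh, a measure of RNA integrity, was 0.93 ± 0.28 in progeroid control and 0.66 ± 0.06 in wild type control mice (log2, SD; exact permutation p = 0.0476, adjusted over 8 comparisons 0.296).

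Targets of NRF2, the regulator of antioxidant and detoxifying enzymes, rose in 7 of 21 cases (8 adjusted over the list alone). The quinone reductase Nqo1 rose 2.42-fold (log2 fold change 1.28 ± 0.15 SE) and the glutathione transferase Gsta2 3.28-fold (1.72 ± 0.21). Camera gave 4.25e-05 for the list, and adjusted p = 0.238 with an estimated correlation. Xenobiotic metabolism genes went both ways, with 3 of 22 higher and 6 lower (3 and 7 adjusted over the list alone). Cyp2c29 fell 2.56-fold (-1.36 ± 0.14), Cyp3a13 rose 1.67-fold (0.74 ± 0.098), and camera gave 0.105. Of the immediate early genes 2 of 16 rose (5 rose and 1 fell adjusted over the list alone): Myc rose 4.76-fold (2.25 ± 0.47) and Klf6 1.75-fold (0.81 ± 0.13), with a camera adjusted p of 0.115.

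Most lipid genes did not pass the test. Of the fatty acid oxidation genes and PPARalpha targets 4 of 28 fell and 1 rose, with the same numbers adjusted over the list alone. Acot2, a mitochondrial acyl-CoA thioesterase, fell 3.33-fold (log2 fold change -1.74 ± 0.24 SE), and without suffixed probe sets its adjusted p was 0.699. The member that rose was Cd36, a fatty acid importer (2.91-fold; 1.54 ± 0.20), which also counts among the lipid droplet genes, of which 3 of 13 rose and 1 fell (3 and 1 adjusted over the list alone). Lpl, lipoprotein lipase, rose 3.71-fold (1.89 ± 0.18). Camera gave 0.00526 for fatty acid oxidation, and adjusted p = 0.582 with an estimated correlation; it gave 0.335 for lipid droplet genes. The median change of 20 cholesterol synthesis genes was 0.099 (camera 0.371). Fatty acid synthesis genes fell in 4 of 19 cases (6 adjusted over the list alone; camera 0.00961), with adjusted p = 0.635 with an estimated correlation. The mean over the list was within the range of the wild type control animals (-0.304 to 0.549) for progeroid control animals 321 (0.377) and 323 (-0.010), and below it for the other 3. Malic enzyme, Me1, fell 2.10-fold (-1.07 ± 0.29) and the elongase Elovl5 1.47-fold (-0.56 ± 0.16). Me1 missed the threshold without progeroid control animals 325 (adjusted p = 0.0596) and 327 (0.0644) or wild type control animal 405 (0.0574), with the sex-linked covariate (0.0737), with the mean of probe sets (0.0743) and without suffixed probe sets (0.208). Elovl5 missed it without progeroid control animals 325 (0.0536) and 327 (0.0825) or wild type control animals 403 (0.0568) and 405 (0.0784), and with the covariate (0.144).

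Autophagy and lysosome genes fell in 3 of 16 cases and rose in 1 (4 and 1 adjusted over the list alone), with Uvrag 1.74-fold lower (log2 fold change -0.80 ± 0.09 SE) and Atg7, which is needed to form autophagosomes, 1.54-fold lower (-0.63 ± 0.099). Camera gave 0.023, and adjusted p = 0.453 with an estimated correlation. Heat shock proteins fell in 4 of 14 cases (4 fell and 1 rose adjusted over the list alone; camera 0.013), with adjusted p = 0.635 with an estimated correlation. The inducible chaperone Hspa1b fell 4.13-fold (-2.05 ± 0.57) and the small heat shock protein Cryab 1.49-fold (-0.58 ± 0.11). Hspa1b missed the threshold without progeroid control animal 321 (adjusted p = 0.0581), without wild type control animals 401 (0.0669), 402 (0.0529) or 404 (0.0665) and with the covariate (0.0566), and Cryab with the mean of its probe sets (0.911). In the growth hormone and IGF1 axis 2 of 12 fell: the deiodinase Dio1 2.21-fold (-1.14 ± 0.27) and the growth hormone receptor Ghr 1.32-fold (-0.40 ± 0.07). Adjusted over the list alone 3 fell and 3 rose, and camera gave 0.796. Tat, tyrosine aminotransferase, fell 1.88-fold (-0.91 ± 0.11); of its 2 lists, gluconeogenesis had 1 of 10 higher and 1 lower (2 and 4 adjusted over the list alone; camera 0.185), and amino acid catabolism and the urea cycle had 3 of 22 lower (camera 0.0994). Pericentral hepatocyte markers had 2 of 9 higher and 1 lower (camera 0.647), erythroid markers 1 of 5 lower (camera 0.647) and secreted plasma proteins of hepatocytes 1 of 15 lower (camera 0.604). The median change was 0.15 over 6 cholangiocyte markers (camera 0.233) and -0.07 over 3 adipocyte markers (camera 0.431). Counting probe sets gave 1793 higher and 1334 lower, and at least 1.5-fold changes were seen in 429 and 196 genes.

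**Figure D2:**
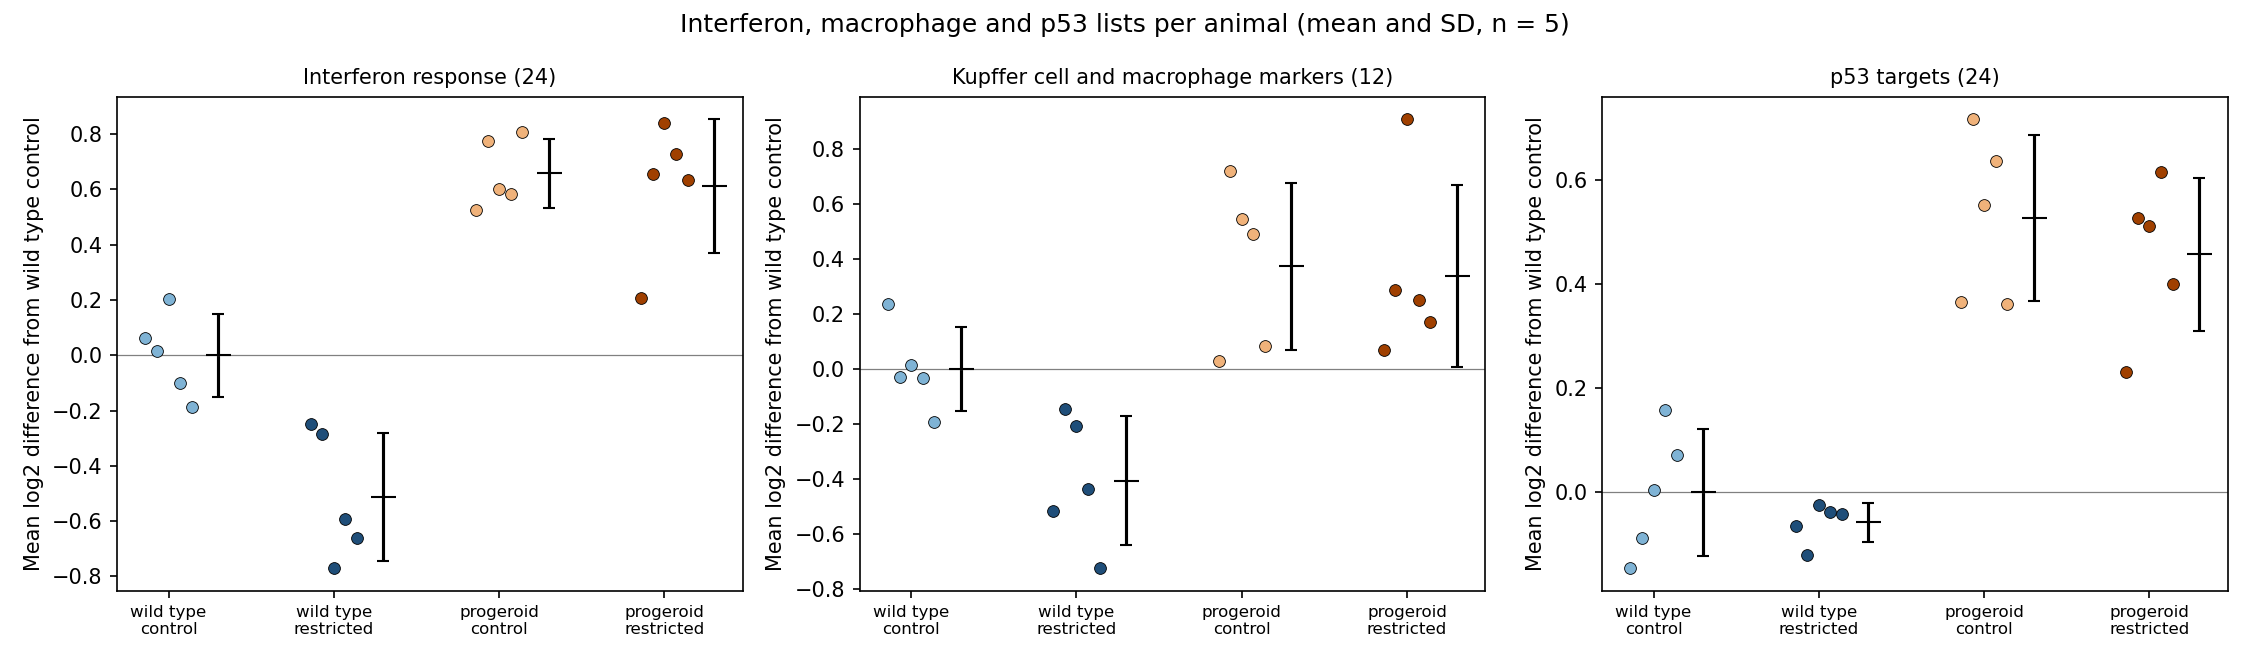
Mean log2 difference from the wild type control mean over the members of the interferon response, Kupffer cell and macrophage, and p53 target lists, 1 point per animal, spread sideways only to separate them; bars show the group mean and SD (n = 5). On the interferon list progeroid control animals lay between 0.524 and 0.807 and restricted wild type animals between -0.769 and -0.25.

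In progeroid mice, the largest rises and falls with restriction included sex-biased liver genes and clock genes. The female-biased gene Acot3, a peroxisomal acyl-CoA thioesterase, rose 27.2-fold (log2 fold change 4.77 ± 0.39 SE, n = 5 per group), the clock-controlled deubiquitinase Usp2 26.4-fold (4.72 ± 0.76), the cytochrome P450 Cyp2b9 16.5-fold (4.05 ± 0.60) and the clock repressor Ciart 11.6-fold (3.53 ± 0.62). Serpina4-ps1 fell 31.6-fold (-4.98 ± 0.49), the steroid reductase Hsd3b5 27.3-fold (-4.77 ± 0.55), the fatty acid elongase Elovl3 26.8-fold (-4.74 ± 0.34) and Cyp4a12a, an arachidonic acid hydroxylase, 17.3-fold (-4.12 ± 0.38). In all, 1186 genes rose and 867 fell. The time of day of sampling is not given, so changes of clock genes cannot be assigned to diet rather than to sampling time.

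All 9 measured male-biased liver genes fell in restricted progeroid mice, and 9 fell adjusted over the list alone. Of 13 female-biased genes 9 rose and 4 did not pass (10 adjusted over the list alone), among them Acot3, Cyp2b9 and the peroxisomal transporter Abcd2 (7.40-fold; 2.89 ± 0.33). Camera gave 1.26e-14 and 2.41e-11, and adjusted p = 0.106 with an estimated correlation for each list. Circadian clock genes rose in 10 of 18 cases and fell in 5 (11 and 5 adjusted over the list alone); Cry2 rose 1.89-fold (0.92 ± 0.12) and Hlf 1.71-fold (0.77 ± 0.10). The list passed camera at 0.00218, with adjusted p = 0.248 with an estimated correlation.

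Some metabolic lists passed camera in progeroid mice, and others did not: fatty acid synthesis had 1 of 19 members lower (camera 0.944), bile acid genes 3 of 18 higher and 2 lower (0.81), and cholesterol synthesis a median change of -0.22 over 20 members (0.327). Fatty acid oxidation genes and PPARalpha targets rose in 10 of 28 cases (14 adjusted over the list alone), including Acot3 and the peroxisomal bifunctional enzyme Ehhadh (1.63-fold; 0.70 ± 0.12). The mean over the list was 0.709 in restricted animal 362 and between 0.122 and 0.249 in the other 4, and Ehhadh was 12.33 in this animal, with the nearest other at 11.75. Camera gave 5.77e-07, and adjusted p = 0.298 with an estimated correlation. Xenobiotic metabolism genes rose in 12 of 22 cases and fell in 1 (13 and 1 adjusted over the list alone), with Cyp2c39 8.86-fold (3.15 ± 0.27) and Cyp2c38 4.89-fold higher (2.29 ± 0.21). Camera gave 5.94e-08 for the list, and adjusted p = 0.195 with an estimated correlation. NRF2 targets rose in 6 of 21 cases and fell in 1 (6 and 2 adjusted over the list alone), with the carbonyl reductase Cbr1 2.16-fold (1.11 ± 0.09) and Nqo1 2.27-fold higher (1.19 ± 0.15); camera gave 0.00944, and adjusted p = 0.452 with an estimated correlation. Gluconeogenesis genes rose in 4 of 10 cases (4 rose and 1 fell adjusted over the list alone), with Tat 1.51-fold (0.59 ± 0.11) and Gpt2 1.27-fold higher (0.35 ± 0.08); camera gave 0.00505, and adjusted p = 0.238 with an estimated correlation. Of the genes of amino acid catabolism and the urea cycle 6 of 22 rose and 2 fell (9 and 3 adjusted over the list alone). Asl, argininosuccinate lyase, rose 1.56-fold (0.64 ± 0.10); camera gave 0.0186, and adjusted p = 0.54 with an estimated correlation. Oxidative phosphorylation genes rose in 3 of 31 cases (1 adjusted over the list alone), with Sdhd higher by 0.32 ± 0.08 on the log2 scale; camera gave 9.78e-05, and adjusted p = 0.433 with an estimated correlation. Ribosomal proteins had 1 of 38 members higher and a median change of 0.11 (camera 1.95e-05), with adjusted p = 0.598 with an estimated correlation. Of the lipid droplet genes 3 of 13 rose (camera 0.168).

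Endoplasmic reticulum and integrated stress response genes fell in 8 of 23 cases and rose in 2 (12 and 3 adjusted over the list alone), with the chaperone Hyou1 1.92-fold (-0.94 ± 0.16) and the disulfide isomerase Pdia6 1.60-fold lower (-0.68 ± 0.13). Camera gave 0.00172, and adjusted p = 0.453 with an estimated correlation. Heat shock proteins fell in 4 of 14 cases (6 adjusted over the list alone), among them Hsp90aa1 (2.36-fold; -1.24 ± 0.24) and the co-chaperone Stip1 (1.59-fold; -0.67 ± 0.19), which missed the threshold without progeroid control animals 321 (adjusted p = 0.0687) and 327 (0.0565) or restricted animal 365 (0.0645); camera gave 0.00136, and adjusted p = 0.581 with an estimated correlation. Of the growth hormone and IGF1 axis 4 of 12 fell (6 fell and 1 rose adjusted over the list alone), with Dio1 2.36-fold (-1.24 ± 0.27) and Ghr 1.40-fold lower (-0.48 ± 0.07); camera gave 0.034, and adjusted p = 0.529 with an estimated correlation. Cdkn1a fell 2.27-fold (-1.19 ± 0.27), while the other p53 targets gave 1 rise and 22 that did not pass (camera 0.346). Interferon genes gave 3 falls and 1 rise of 24 (camera 0.512), with Stat2 1.60-fold lower (-0.67 ± 0.10). Of the acute phase genes 4 of 22 fell and 1 rose (camera 0.265), with the serum amyloid Saa3 2.26-fold lower (-1.18 ± 0.18). Repair genes rose in 8 of 24 cases and fell in 2 (9 and 4 adjusted over the list alone), with Brca1 2.17-fold (1.12 ± 0.19) and Fancc 1.89-fold higher (0.92 ± 0.10); camera gave 0.0154, and adjusted p = 0.298 with an estimated correlation. Erythroid markers passed camera at 0.0298 with 1 of 5 members lower, the heme synthesis gene Alas2 (2.20-fold; -1.14 ± 0.19), and adjusted p = 0.248 with an estimated correlation. Lymphocyte markers fell in 2 of 15 cases (3 adjusted over the list alone; camera 0.101), among them Cd4 (1.23-fold; -0.29 ± 0.08), at an adjusted p of 0.229 with the mean of its probe sets. Counting probe sets gave 2165 higher and 1550 lower, and at least 1.5-fold changes were seen in 329 and 219 genes. Without progeroid control animal 323, 561 genes fell.

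In wild type mice, restriction changed more genes, and the largest changes again included those of sex-biased genes, though Sult1e1 and Serpina4-ps1 are in neither sex-biased list. Cyp2b9 rose 132-fold (log2 fold change 7.05 ± 0.60 SE, n = 5 per group), Sult1e1 48.6-fold (5.60 ± 0.51), the sulfotransferase Sult3a1 44.6-fold (5.48 ± 0.57) and the steroid hydroxylase Cyp17a1 28.9-fold (4.85 ± 0.50). Hsd3b5 fell 318-fold (-8.31 ± 0.55), Cyp4a12a 241-fold (-7.91 ± 0.38), Elovl3 121-fold (-6.92 ± 0.34) and Serpina4-ps1 32.5-fold (-5.02 ± 0.49). In all, 1696 genes rose and 2146 fell. The unknown time of sampling limits the reading of clock genes here too.

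Male-biased genes fell in 8 of 9 cases (8 adjusted over the list alone). Female-biased genes rose in 9 of 13 cases and fell in 1 (10 and 1 adjusted over the list alone), with the repressor Cux2 25.9-fold higher (4.70 ± 0.41). Camera gave 8.83e-13 and 1.17e-09; with an estimated correlation the male-biased list had adjusted p = 0.106 and the female-biased list adjusted p = 0.154. Clock genes rose in 10 of 18 cases and fell in 2 (12 and 2 adjusted over the list alone), with Cry2 1.90-fold higher (0.93 ± 0.12) and Nfil3 5.50-fold lower (-2.46 ± 0.34); camera gave 0.00505, and adjusted p = 0.298 with an estimated correlation.

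**Figure D3:**
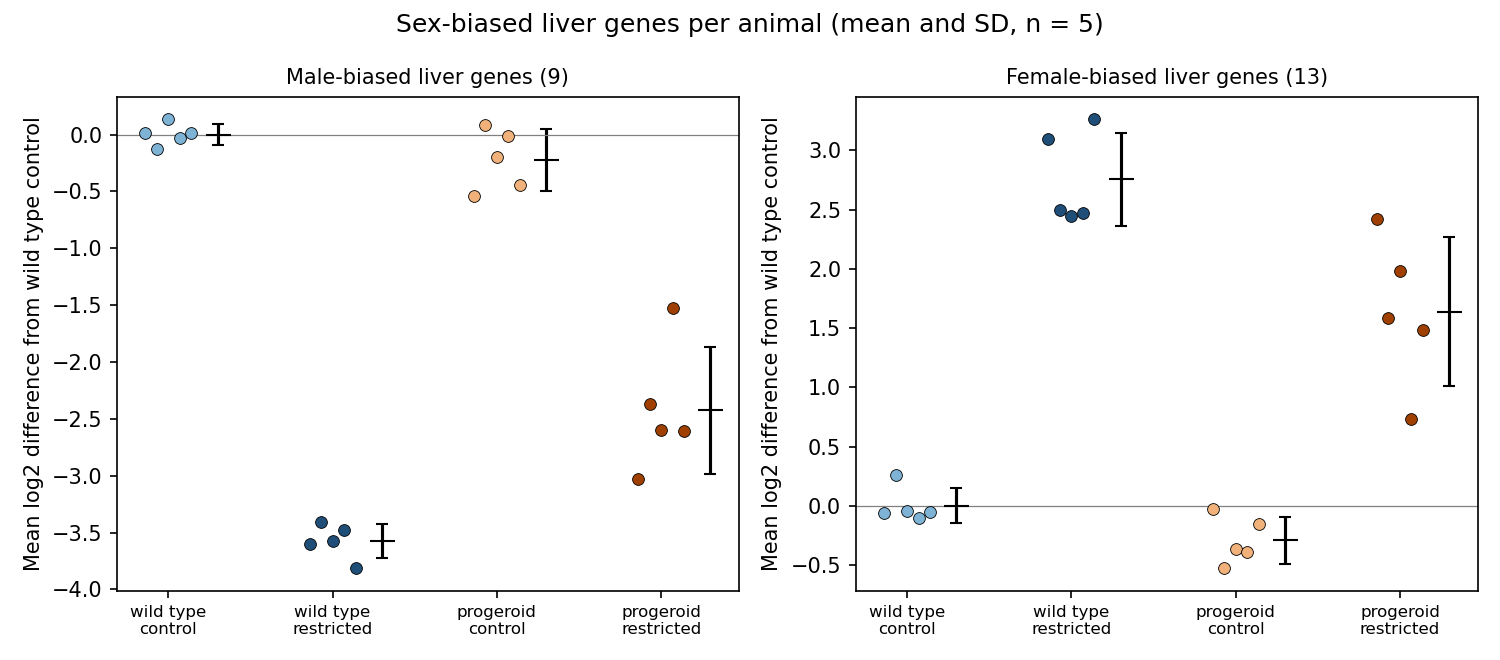
Mean log2 difference from the wild type control mean over 9 male-biased and 13 female-biased liver genes, 1 point per animal, spread sideways only to separate them; bars show the group mean and SD (n = 5). On the male-biased list restricted wild type animals lay between -3.81 and -3.41 and restricted progeroid animals between -3.03 and -1.52.

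Ribosomal protein genes rose in 26 of 38 cases in restricted wild type mice (32 adjusted over the list alone) by small amounts, with Rpl32 at 1.33-fold (log2 fold change 0.41 ± 0.075 SE) and Rpl3 at 1.28-fold (0.35 ± 0.06). Camera gave 1.26e-14, and adjusted p = 0.34 with an estimated correlation. Oxidative phosphorylation genes rose in 10 of 31 cases (13 adjusted over the list alone), among them Sdhd (1.37-fold; 0.46 ± 0.08) and Cyc1 (1.18-fold; 0.24 ± 0.06); camera gave 5.18e-05, and adjusted p = 0.422 with an estimated correlation. Heat shock proteins fell in 11 of 14 cases (12 adjusted over the list alone), with Hspa1b 14.3-fold (-3.84 ± 0.57) and Hspb1 2.79-fold lower (-1.48 ± 0.24). Camera gave 4.45e-06, and adjusted p = 0.433 with an estimated correlation.

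Interferon genes fell in 12 of 24 cases (17 adjusted over the list alone), with the antiviral gene Rsad2 2.81-fold (log2 fold change -1.49 ± 0.19 SE) and the GTPase Irgm1 1.67-fold lower (-0.74 ± 0.12); camera gave 6.89e-06, and adjusted p = 0.491 with an estimated correlation. Kupffer cell and macrophage markers fell in 4 of 12 cases (8 fell and 1 rose adjusted over the list alone), among them Adgre1, which encodes F4/80 (1.91-fold; -0.94 ± 0.14), and Clec4f (1.65-fold; -0.72 ± 0.13). Camera gave 0.00526, and adjusted p = 0.635 with an estimated correlation. Lymphocyte markers fell in 3 of 15 cases (3 adjusted over the list alone), with granzyme A, Gzma, 1.34-fold lower (-0.43 ± 0.07) and Cd4 1.22-fold lower (-0.29 ± 0.08; adjusted p = 0.0883 with the mean of its probe sets); camera gave 0.0267, and adjusted p = 0.433 with an estimated correlation. Endothelial markers gave 1 fall of 13 (camera 0.333), and pancreatic acinar markers 1 fall of 6 (camera 0.572).

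In restricted wild type mice fatty acid synthesis genes rose in 4 of 19 cases (4 adjusted over the list alone), with the triglyceride lipase family gene Pnpla3 6.25-fold (log2 fold change 2.64 ± 0.69 SE) and the pyruvate kinase Pklr 2.09-fold higher (1.07 ± 0.25). Camera gave 0.0223, and adjusted p = 0.669 with an estimated correlation. Cholesterol synthesis genes rose in 2 of 20 cases (1 adjusted over the list alone), with lanosterol synthase, Lss, 3.51-fold (1.81 ± 0.37) and squalene synthase, Fdft1, 1.74-fold higher (0.80 ± 0.27). Fdft1 missed the threshold without wild type control animals 401 (adjusted p = 0.0833), 402 (0.0892) or 404 (0.098) or restricted animals 421 (0.0633), 422 (0.0831) or 425 (0.0564), and with a trended robust prior (0.0588). For the list camera gave 0.00716, and adjusted p = 0.669 with an estimated correlation. Of the fatty acid oxidation genes and PPARalpha targets 9 of 28 fell and 4 rose (10 and 4 adjusted over the list alone; camera 0.341): the lipid droplet coat protein Plin2 fell 2.58-fold (-1.37 ± 0.17) and the transcription factor Creb3l3 2.16-fold (-1.11 ± 0.12), while Acot3 rose 18.4-fold (4.20 ± 0.39). Gluconeogenesis genes rose in 5 of 10 cases and fell in 1 (5 and 1 adjusted over the list alone). Gpt2 rose 1.35-fold (0.44 ± 0.08) and the member that fell was the glucose-6-phosphatase gene G6pc (2.90-fold; -1.54 ± 0.32). Camera gave 0.0156, and adjusted p = 0.298 with an estimated correlation. Xenobiotic metabolism genes rose in 10 of 22 cases and fell in 3 (11 and 3 adjusted over the list alone), with Cyp2c39 4.64-fold higher (2.21 ± 0.27); camera gave 0.00247, and adjusted p = 0.433 with an estimated correlation. Genes of amino acid catabolism and the urea cycle rose in 7 of 22 cases and fell in 2 (camera 0.0563), with proline dehydrogenase, Prodh, 2.09-fold higher (1.06 ± 0.12). Bile acid synthesis and transport genes fell in 8 of 18 cases and rose in 5 (camera 0.696). The oxysterol hydroxylase Cyp7b1 fell 4.28-fold (-2.10 ± 0.21) and the reductase Akr1d1 rose 1.88-fold (0.91 ± 0.075). Of 7 periportal hepatocyte markers 3 rose and 1, Cyp2f2, fell 2-fold (camera 0.535). Counting probe sets gave 4449 higher and 4095 lower, and at least 1.5-fold changes were seen in 488 and 598 genes.

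On the restricted diet, progeroid livers still had more Afp than wild type livers (14.3-fold; log2 fold change 3.84 ± 0.17 SE, n = 5 per group). Clec2h was 13.2-fold (3.73 ± 0.55), the glutathione peroxidase gene Gpx6 9.96-fold (3.32 ± 0.22) and Olig1 8.01-fold higher (3.00 ± 0.25). Lower in progeroid mice were Cyp2b10 (17.7-fold; -4.15 ± 0.70), Cyp2b13 (15.3-fold; -3.93 ± 0.46), Cyp17a1 (13.1-fold; -3.71 ± 0.50) and Pnpla3 (12.5-fold; -3.64 ± 0.69). In all, 2018 genes were higher and 930 lower.

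Interferon genes were higher in restricted progeroid than in restricted wild type mice in 22 of 24 cases (22 adjusted over the list alone), with Usp18 7.51-fold (log2 fold change 2.91 ± 0.28 SE) and Rsad2 4.21-fold higher (2.08 ± 0.19). Camera gave 5.05e-20, and adjusted p = 0.188 with an estimated correlation. Kupffer cell and macrophage markers were higher in 10 of 12 cases (11 adjusted over the list alone), with Clec4f at 1.85-fold (0.89 ± 0.13) and Adgre1 at 1.57-fold (0.65 ± 0.14); camera gave 3.46e-07, and adjusted p = 0.422 with an estimated correlation. NRF2 targets were higher in 11 of 21 cases (15 adjusted over the list alone; camera 5.54e-06), with adjusted p = 0.195 with an estimated correlation. Targets of p53 were higher in 13 of 24 cases (15 adjusted over the list alone), with Cdkn1a at 2.35-fold (1.23 ± 0.27); camera gave 2.49e-05, and adjusted p = 0.248 with an estimated correlation. Fatty acid synthesis genes were lower in 13 of 19 cases and higher in 1 (13 and 2 adjusted over the list alone), among them Pnpla3, Pklr (2.63-fold; -1.39 ± 0.25) and the carbohydrate-responsive regulator Mlxipl (1.47-fold; -0.56 ± 0.13). Camera gave 1.06e-06, and adjusted p = 0.433 with an estimated correlation. Cholesterol synthesis genes were lower in 1 of 20 cases (camera 0.00273), with adjusted p = 0.652 with an estimated correlation. Fatty acid oxidation genes and PPARalpha targets were higher in 9 of 28 cases (9 adjusted over the list alone), including Cd36 (2.64-fold; 1.40 ± 0.20); camera gave 0.00107, and adjusted p = 0.534 with an estimated correlation. Male-biased genes were higher in 6 of 9 cases (7 adjusted over the list alone), with Cyp4a12a at 7.39-fold (2.89 ± 0.38), and female-biased genes lower in 5 of 13 cases and higher in 2 (6 and 2 adjusted over the list alone), with Cyp2b9 4.82-fold lower (-2.27 ± 0.60). Camera gave 0.000244 and 0.0154; with an estimated correlation the male-biased list had adjusted p = 0.36 and the female-biased list adjusted p = 0.54. Lists of lipid droplet, stress response, acute phase, cell cycle, oxidative phosphorylation, ribosomal, immediate early and stellate cell genes also passed camera, between 0.00187 and 0.0484, with adjusted p between 0.298 and 0.682 with an estimated correlation. Counting probe sets gave 3182 higher and 1992 lower, and at least 1.5-fold differences were seen in 728 and 207 genes. The mean of the Y-linked genes minus Xist was 0.40 higher in restricted progeroid mice (exact permutation p = 0.00794, the smallest possible), and with this measure as a covariate 1028 genes were higher and 388 lower.

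The diet effect itself differed between genotypes for 240 genes, 176 with a more positive and 64 with a more negative change in progeroid mice. Cyp4a12a (log2 difference 3.80 ± 0.54 SE, n = 5 per group) and Hsd3b5 (3.55 ± 0.77) fell in both genotypes but less in progeroid mice. Spc25, a kinetochore component, differed by 2.40 ± 0.28 and Mfsd2a by 2.61 ± 0.58. Mfsd2a was 6.73 ± 1.04 (SD) in progeroid control mice and 9.53 ± 0.63 after restriction, against 9.86 ± 0.39 and 10.05 ± 0.69 in wild type mice. The most negative differences were those of Sult1e1 (-3.84 ± 0.72), Cyp2b13 (-3.75 ± 0.65), Cyp17a1 (-3.15 ± 0.70) and Slc22a26 (-2.38 ± 0.53). Sult1e1 was already higher in progeroid control mice, at 7.69 ± 0.99 (SD) against 4.44 ± 0.125 in wild type control mice. After restriction it was 9.46 ± 1.05 in progeroid and 10.05 ± 1.05 in wild type mice.

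Of the 240 genes, 97 fell in wild type mice and were not called in progeroid mice, and 43 rose in wild type mice and were not called in progeroid mice. A further 40 rose and 6 fell in progeroid mice and were not called in wild type mice. Both fell for 23 and both rose for 12, while 14 rose in progeroid and fell in wild type mice, 3 did the opposite, and 2 were called in neither. Fatty acid oxidation genes and PPARalpha targets had 7 of 28 members with a more positive change in progeroid mice (13 adjusted over the list alone), among them Acot2 (1.55 ± 0.34), Plin2 (1.16 ± 0.24) and Creb3l3 (1.09 ± 0.16). Camera gave 9.25e-11, and adjusted p = 0.195 with an estimated correlation. Male-biased genes had 3 of 9 members more positive and 1 more negative (7 and 1 adjusted over the list alone), with Elovl3 at 2.18 ± 0.47; camera gave 2.12e-05, and adjusted p = 0.298 with an estimated correlation. Interferon genes had 2 of 24 members more positive (8 adjusted over the list alone), with Rsad2 at 1.14 ± 0.27; camera gave 5.66e-06, and adjusted p = 0.488 with an estimated correlation. The median difference was -0.69 over 20 cholesterol synthesis genes (camera 1.8e-05) and -0.12 over 38 ribosomal proteins (camera 3.46e-07). With an estimated correlation these lists had adjusted p = 0.556 and adjusted p = 0.54. The fatty acid synthesis, macrophage, heat shock and endoplasmic reticulum stress lists also passed camera (0.00494, 0.00853, 0.0101 and 0.0186), with adjusted p = 0.635 for each of the first 3 and 0.582 for the last with an estimated correlation.

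The count of 240 varied widely, in both directions, when 1 animal was left out, and no single animal accounted for it. It was 103, 149 and 490 without restricted wild type animals 423, 424 and 421. Without restricted progeroid animals 369, 368, 366 and 362 it was 129, 143, 146 and 386. It was 146 without progeroid control animal 321, and 138 and 148 without wild type control animals 401 and 403. Leaving out any other animal gave between 166 and 263. With a trended robust prior Hsd3b5 (adjusted p = 0.052), Mfsd2a (0.055), Cyp17a1 (0.0586) and Slc22a26 (0.0531) missed the threshold. Hsd3b5 also missed it without animals 369 (0.0522) or 423 (0.0551). Cyp17a1 did so without any of 321, 327, 366, 369, 401, 404, 423 or 424 (0.0502 to 0.0596), Mfsd2a without any of 323, 365, 369, 401, 402, 403, 423 or 424 (0.0503 to 0.0586), and Slc22a26 without any of 365, 368, 369, 401 or 403 (0.0504 to 0.0597).

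**Figure D4:**
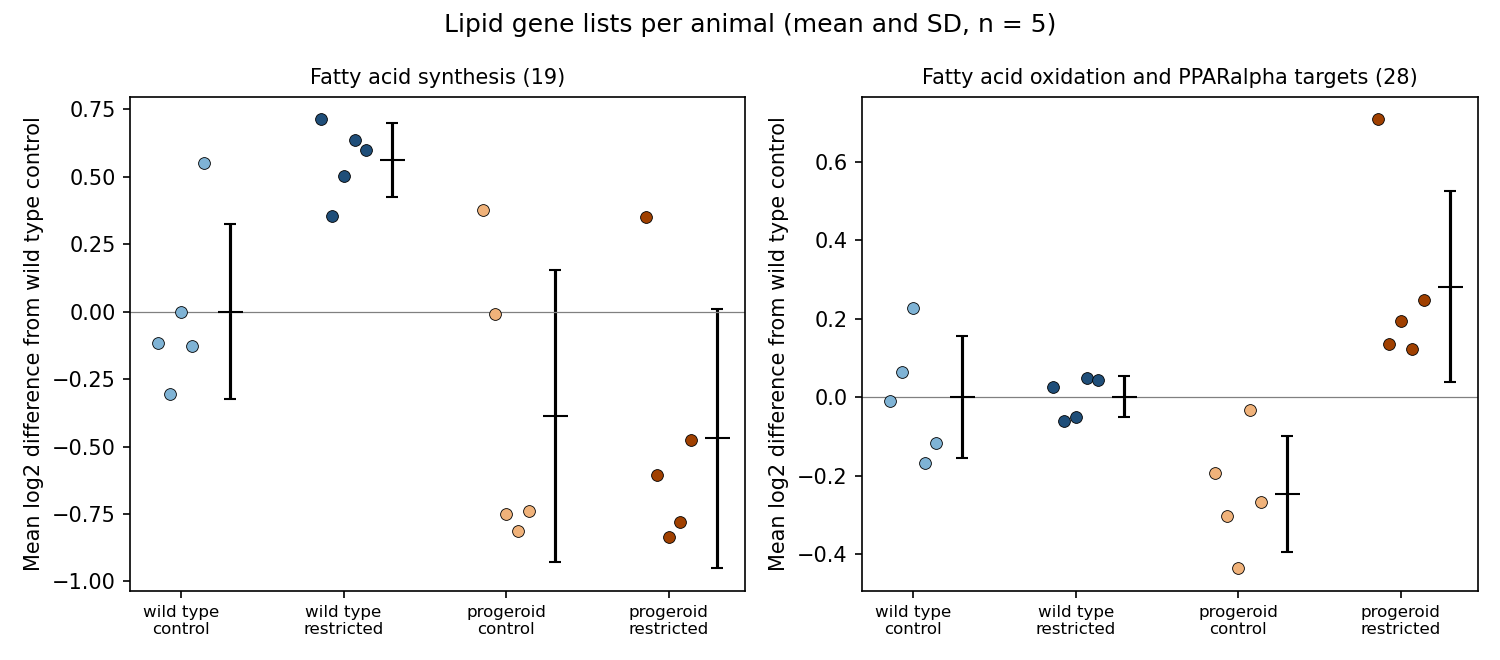
Mean log2 difference from the wild type control mean over 19 fatty acid synthesis genes and over 28 fatty acid oxidation genes and PPARalpha targets, 1 point per animal, spread sideways only to separate them; bars show the group mean and SD (n = 5). On the synthesis list restricted wild type animals lay between 0.355 and 0.714 and restricted progeroid animals between -0.837 and 0.35.

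Across genes, the diet effects in the 2 genotypes correlated at r = 0.701 (jackknife SE 0.0836). Both rose for 672 genes and both fell for 536, against 118 and 109 for independent lists, and 17 genes went opposite ways. Of the 3842 genes called in wild type mice, 87.5% changed with the same sign in progeroid mice. The genotype effects on the 2 diets correlated at r = 0.579 (jackknife SE 0.0818). Of the 1883 genes called on the control diet, 959 were called the same way on the restricted diet, 13 the opposite way, and 1694 had the same sign.

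The genotype effect on control diet and the wild type diet effect share the wild type control arrays and correlated at r = 0.175 (jackknife SE 0.0833). Both were higher for 278 genes, both lower for 243 and opposite for 205, against 114, 92.6 and 217 for independent lists. Simulated groups without any effect gave a median r of 0.529 and a median covariance of 0.00831, at most 0.0212, from the shared controls alone, beside an observed covariance of 0.0188. With the control arrays split between the contrasts, r averaged 0.0991 and ranged from -0.00626 to 0.165, and on average 108 genes were higher in both, 90.3 lower in both and 92.8 opposite.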

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

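The tests of Xist, of growth hormone response genes, of cell type markers and of the clock score were chosen only after the result they bear on had been seen; the other tests reported here were fixed before. The number of genes called was compared with that of other splits of the same animals, 100 per comparison with the real one included. The real split gave the highest count in each case: 1883 against at most 227 for genotype on control diet, 2053 against 397 for diet in progeroid mice, 3842 against 489 for diet in wild type mice, and 2948 against 553 for genotype on restricted diet. For the difference of diet effects, permuted residuals of an additive model gave at most 2 genes against 240. In each comparison 1 of 100 reached the real count, the real one itself, and the share could not be lower than this. Mixed splits and permuted residuals carry the real difference in their spread, which lowers their counts. The real counts were thus the highest of those examined, but the test cannot exclude chance. Nor can it separate genotype or diet from anything else that follows the groups.

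With restriction, male-biased genes fell in 9 of 9 cases in progeroid and 8 of 9 in wild type mice. Female-biased genes rose in 9 of 13 cases in each genotype, and 1 fell in wild type mice. With an estimated correlation the camera adjusted p of these lists lay between 0.106 and 0.154. Female animals among the restricted groups are argued against by Xist, whose larger diet difference was -0.178, with Eif2s3y at 9.58 or above in every array. The shift did not rest on probe sets with a suffix. The female-biased list in wild type mice had a median change of 2.09 with them (13 members) and without them (11 members). The male-biased list was at -2.10 with them (9 members) and at -4.62 on the 6 members left. Of the members left, 0 moved to another probe set, so this test only dropped members. Plain probe sets can also cross-hybridise, so it cannot decide whether cross-hybridisation contributed. Lower growth hormone signalling stays open as a candidate explanation: in wild type mice 2 of Igf1, Igfals, Socs2 and Cish fell (Igf1 by 0.23 and Igfals by 0.68), but Socs2 rose by 2.35. In progeroid mice Igfals fell by 0.53, and Igf1 (-0.18), Socs2 (0.97) and Cish (-0.74) did not pass. The wild type median, 0.539, met the criterion set against this explanation (a median above 0); that criterion was set aside after the result was seen, because the members went both ways with an SD of 1.4. The diet itself, the timing of meals and the pattern of hormone release stay open and were not tested.

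Interferon genes were higher in progeroid livers in 17 of 24 cases on control diet and 22 on restriction, and macrophage markers in 2 and 10 of 12 cases; macrophage scores of progeroid control animals 321 and 327 (0.029 and 0.083) lay within the wild type control range. A lower share of hepatocytes would raise markers of all other cells alike. On the restricted diet endothelial markers changed by 0.671 less than Kupffer cell markers on average (difference -0.671). The permutation p was 2e-05 over genes, which are not independent. This argues against an equal rise of all other cells, but rests on endothelial markers alone. Stellate cell markers also passed camera on both diets, and neutrophil and monocyte markers rose on control diet. A lower share of hepatocytes is therefore not excluded. More Kupffer cells or macrophages cannot be told apart from a response within cells: interferon genes rose more than the markers by 0.284 on control diet and by 0.382 on restriction, with permutation p = 0.0623 and 0.0978. Of the 12 Kupffer cell markers 0 are in another list, and liver itself holds these cells; the one with the highest signal, Cd5l, was 10.80 ± 0.19 (SD, n = 5) in wild type and 11.22 ± 0.32 in progeroid control mice. Relative to wild type control mice, the mean over the interferon list was 0.658 in progeroid control and 0.613 in progeroid restricted mice. In wild type restricted mice it was -0.511. For the macrophage list these means were 0.374, 0.338 and -0.405. The wider difference on restriction thus came with a fall in wild type mice rather than a rise in progeroid mice. The genotype stays a candidate explanation, untested beyond the comparison.

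Fatty acid synthesis genes were lower in progeroid than in wild type mice on restriction in 13 of 19 cases, with a median of -1.36. The mean over the list was 0.350 in restricted progeroid animal 362, close to the lowest restricted wild type animal (0.355), and between -0.837 and -0.477 in the other 4. No single animal accounts for it, since leaving out each of the 10 animals in turn left the median at -1.21 or lower. Sampling at different clock times could contribute and cannot be excluded: a clock score (11 genes high at the end of the light phase minus 5 high at the end of the dark phase) differed by 0.169 between the restricted groups (exact permutation p = 0.595). Its 95% interval, -0.595 to 0.93, exceeds the bound of 0.512, set as a share of the wild type diet effect of 2.05. The amounts of food and the genotype stay open too; the amount for restricted progeroid mice is not given by name.

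The diet effect differed between genotypes, by a test of the difference, for 19 of the genes named in the text and for 240 of all 17097. The naming rule itself takes the 4 largest rises and 4 largest falls of this difference. The count of 19 is therefore no result about the named genes. On the log2 scale, progeroid minus wild type, the differences were 3.80 for Cyp4a12a, 3.55 for Hsd3b5, 2.61 for Mfsd2a, 2.40 for Spc25, 2.18 for Elovl3, 1.97 for Gpx6, 1.68 for Olig1, 1.55 for Acot2, 1.16 for Plin2, 1.14 for Rsad2, 1.09 for Creb3l3, 0.88 for Cyp2c29 and 0.73 for Cyp2f2. They were negative for Sult1e1 (-3.84), Cyp2b13 (-3.75), Cyp17a1 (-3.15), Slc22a26 (-2.38), Pls1 (-1.69) and Lcn2 (-1.50).

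Single animals stood apart in 26 of 432 sets of 5 values examined, where chance gives about 21.6. The gap to the nearest animal is given as a share of the range of the group, with 0.71 as the limit. Progeroid control animal 327 had high Ciart (0.853) and Usp2 (0.747) and low Elovl3 (0.739) and G6pc (0.818), and its clock score was 2.03 where the other 4 lay between -1.47 and 0.02. Its 3' minus 5' difference of Gapdh was 1.38, the highest of its group. Restricted progeroid animal 362 had high Pnpla3 (0.903), Ehhadh (0.849) and Pklr (0.756). Restricted wild type animal 424 had high Creld2 (0.927), low Cux2 (0.745) and low Prodh (0.865). Restricted progeroid animal 368 had high Afp (0.757) and Alas2 (0.756), animal 366 high Cyp2b13 (0.763) and Vsig4 (0.755), and animal 365 low Spc25 (0.86). Wild type control animal 402 had high Cyp2b9 (0.786) and Cyp3a13 (0.892), animal 403 high Akr1d1 (0.742) and animal 405 high Pnpla3 (0.741). Progeroid control animal 321 had high Pnpla3 (0.72) and low Ghr (0.764), and animal 326 high Gzma (0.77). Restricted wild type animals 421, 422, 423 and 425 had low Cyp3a13 (0.731), Cyp2c38 (0.721), Sult3a1 (0.752) and Elovl5 (0.766), in that order.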

How the results depend on the processing

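All alternatives were planned. The 200 results given by the rule for named genes, each a gene in a contrast, kept direction and side of the threshold in 199 cases with median centring, 198 with array weights, 195 with the mean of all probe sets, 193 with a trended robust prior and 187 with the sex covariate; the others kept their direction and lost their call. So did 136 of 4000 values with 1 animal left out. Without the lowest tertile of genes all 196 that remained kept both. Without suffixed probe sets 159 of 166 kept both, 6 lost their call, and Ercc1 changed sign (0.020), because a flat probe set then stands for it. Dim values limit detection: 8276 genes had a wild type control mean under 5. No paired analysis was made because the sample labels give no litter or other pairing of animals. The comparison of long and short genes was not run.

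Counting all probe sets gave, higher and lower, 1793 and 1334 (genotype, control diet), 2165 and 1550 (diet, progeroid), 4449 and 4095 (diet, wild type), 3182 and 1992 (genotype, restricted diet) and 122 lower for the difference of diet effects. More features were tested. For diet in wild type mice the more frequent direction also changed, since by gene 1696 rose and 2146 fell. Why it changed was not tested. At least 1.5-fold gave 429 and 196, 329 and 219, 488 and 598, and 728 and 207 by construction. The sex covariate gave 1028 and 388 for genotype on restricted diet, and 42 lower for the difference of diet effects. Array weights gave 110 there. Every array had Eif2s3y at 9.575 or above and Xist at 4.501 or below, so the covariate showed no difference of sex. It was 0.397 higher in restricted progeroid than in restricted wild type mice (exact permutation p = 0.00794). The covariate thus overlapped with genotype on the restricted diet, and adjusting for it can remove part of that difference. The cause of the changed counts was not tested. Lists past the threshold numbered 67 with camera, 57 with fry and 0 with an estimated correlation (24 at an unadjusted p under 0.05).

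With 1 animal left out, genes higher and lower ranged from 923 to 1175 and 577 to 768 (genotype, control diet), 872 to 1199 and 561 to 920 (diet, progeroid; 561 without progeroid control animal 323), 1393 to 1749 and 1758 to 2217 (diet, wild type), and 1625 to 2163 and 633 to 1006 (genotype, restricted diet). For the difference of diet effects they ranged from 77 to 364 and 26 to 126, both lowest without restricted wild type animal 423 and highest without 421. The Ercc1 difference ranged from -1.30 to -1.19, and the correlations from 0.647 to 0.733 (diet effects), 0.539 to 0.624 (genotype effects) and 0.141 to 0.219 (genotype and wild type diet).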

Other observations

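The test of the fetal and imprinted list on control diet was fixed before its values were seen; its values on restriction and those of Meg3 were chosen for the text after they were seen. Afp was joined by Meg3, a maternally expressed imprinted RNA, which rose 5.49-fold in progeroid livers on control diet (log2 fold change 2.46 ± 0.32 SE, limma adjusted p = 3.04e-05) and 2.33-fold on restriction (1.22 ± 0.32, adjusted p = 0.0111). The hypothesis that fetal and imprinted growth genes rise as a group in progeroid livers was tested on 8 measured of 12 listed genes, without Afp and Meg3. The median change on control diet was -0.00473, 1 of 8 rose (1 adjusted over the list alone), and camera gave 0.528 across all genes. This met the criterion set against the hypothesis. However, 4 of the 8 members were near the lower end of the scale, so the test cannot decide for the list as a whole. The criterion covered the control diet only. Of the 8, 4 had levels under 5 in wild type control mice, where folds are understated: Igf2, Dlk1, Ndn and Igf2bp3 (3.68, 3.84, 4.17 and 3.42). Small rises of these could be missed, but Afp rose from a level of 4.12. Among members with higher levels, Peg3 (-0.057), Cdkn1c (-0.072) and Grb10 (0.013) did not pass. The member that rose was Plagl1, a growth regulator of the imprinted gene network, at 1.80-fold (0.85 ± 0.19). On restriction 3 of 8 were higher (4 adjusted over the list alone): Plagl1 by 0.89, Ndn by 0.45 and Igf2bp3 by 0.28. There the median change was 0.203. Camera gave an unadjusted p of 0.0384, and 0.0955 with an estimated correlation, and fry gave 0.0013. The median, the first camera p and the number called reached the thresholds set for a rise as a group. Those thresholds were set for the control diet, so the hypothesis stays open on restriction.

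Clock scores spread widely among animals on the control diet and little among restricted ones. In wild type control mice they ran from -1.43 to 1.51 and in progeroid control mice from -1.47 to 2.03, whereas restricted animals lay between 2.02 and 3.28 in wild type and between 2.02 and 3.12 in progeroid mice. The wild type diet effect on the score was 2.05 (exact permutation p = 0.00794, the smallest possible). In progeroid mice the mean score was -0.151 on the control diet and 2.76 on restriction. The time of day at which livers were taken is not given in the sources used here. A diet effect on clock genes therefore cannot be told apart from sampling at different clock times. The same holds for any other diet change that follows the clock.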
